A study of Homo sapiens with 18 samples.

How the data were processed

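Accessible chromatin was measured by Omni-ATAC-seq in T47D cells, an established human breast carcinoma line that expresses the progesterone receptor. In this assay the Tn5 transposase cuts open DNA and inserts sequencing adapters, so the number of reads in a region follows how open it is. Per the labels' protocols, the cells were kept without serum and then given R5020 (promegestone, a synthetic progestin) at 0.1 nM or 10 nM, or the vehicle, for 6 h or 18 h. The labels put 3 libraries in each of 6 groups, 18 libraries in all. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be partly technical.

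The values are raw read counts per region in 1 table of all libraries, deposited by the authors without normalization. Per the submitters' processing notes, the tools were BWA and MACS2 and the build was hg19; their versions, the read filters, any shift of reads for the Tn5 insertion and the way the region list was merged are not given in the sources used here. One list of 132604 regions serves every library, with a median width of 386 bp and a range of 138 to 7583 bp, and no neighbouring regions overlap. The list was drawn from these cells, so a region that was open in few libraries can be missing from it. Regions are named here by their hg19 chromosome, start and end exactly as the table gives them; whether the start counts from 0 or from 1 is not stated there. Gene names, gene lists and sequence motifs were not analysed here, because the annotation table at hand is of another build (GRCh38.p14) and coordinates were not converted. Each region is therefore described by its position, its counts and its response.

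Each column was matched to its sample by the sample's name. Totals of counts in regions ran from 8756311 to 39984217 per library. Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with its default settings (minimum count 10, minimum total 15) kept 132304 regions and left out 300, TMM factors scaled the libraries, and the quasi-likelihood test (glmQLFit and glmQLFTest) was run in 1 fit of all 18 libraries with a mean per group and 12 residual degrees of freedom. Comparisons were each dose with the vehicle and the doses with each other at each time, the vehicle between times, and 3 interactions that test whether a response or the dose difference changed between 6 h and 18 h. A region was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Levels are given as CPM, the counts of a region relative to the TMM-scaled library size as edgeR's cpm function gives them; log2 CPM used a prior count of 2.

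The rule for named regions was fixed before the data were examined. It took, for each comparison of a dose with vehicle, the 8 called regions with the largest rise and the 8 with the largest fall in log2 fold change, among those with a mean log2 CPM of at least 1 and no overlap between the replicate CPM values of the groups, and 3 in each direction for the other comparisons. Groups of 3 separate by chance in 10% of regions; 44.7% of tested regions separated between 10 nM and vehicle at 6 h, 13.6% between 0.1 nM and vehicle at 6 h, and 9.51% between the vehicle groups of the 2 times.

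Pairs of replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom between 3.28 and 27.7, so no library was counted as a repeat of another. The labels number the replicates 1 to 3 in each group. Deviations from the group means correlated above 0.1 in each same-numbered pair between the doses at 18 h (r = 0.60, 0.19 and 0.45 across regions). The same held between the vehicle groups of the 2 times (0.32, 0.12 and 0.45). The numbers may thus pair the libraries of those comparisons, a pairing that comes from the data and not from the labels. In each group of these comparisons the percent of counts in the 5000 strongest regions also fell from replicate 1 to 3. At 18 h it was 39.4, 36.7 and 33.4 with 0.1 nM and 37.2, 33.0 and 31.1 with 10 nM. The correlations alone therefore do not show a shared culture or day. The main fit has no block, so its counts and p-values there are unpaired. A fit with the replicate number as a block is given beside it for those comparisons. The other comparisons did not meet the limit of 0.1.

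The steps were tested on simulated counts drawn from the vehicle means, the real library sizes and the estimated dispersions, with 200 regions of at least 1 CPM changed in each treated group. Of 100 regions changed by 4-fold, the test called 71 for 10 nM against vehicle at 6 h, 68 for 0.1 nM at 6 h, 68 for 10 nM at 18 h and 70 for 0.1 nM at 18 h; of 100 changed by 2-fold, it called 4, 11, 9 and 8. Calls among regions left unchanged numbered 8, 4, 6 and 8 in the same order. A further simulation gauged what sharing vehicle libraries adds to the covariance of the log2 fold changes of the doses. All libraries of a time, vehicle included, were drawn 10 times from the vehicle means of that time. Each region was drawn independently, so these draws hold no shift of a whole library across regions.

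Alternatives fixed before the data were examined were DESeq2 size factors, library totals only, loess normalization, no low-count filter, a minimum of 20 counts in every library of a group, DESeq2 1.42.0's Wald test, only the 2 groups compared in the fit, the replicate number as a block, a log2 fold change of at least 1, an overlap limit of adjusted p under 0.01, and leaving out each library in turn. Added after seeing the data were the percent of counts in the 5000 strongest regions as a covariate, leaving out the 2 libraries that lay apart, leaving out the 100 regions with the most counts, and, for sets of regions measured at the other time, library totals, a limit of 0.01, the differences between same-numbered libraries of the doses at 18 h, that percent as a covariate in a linear model of the library medians, and leaving out each library. Counts on all 7 mitochondrial regions were 0 and these were removed by the filter. Figures were drawn with matplotlib 3.10.9.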

Results

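The series asks how breast cancer cells respond to different levels of a progestin. Chromatin accessibility was measured by Omni-ATAC-seq in T47D cells treated with vehicle, 0.1 nM R5020 or 10 nM R5020 for 6 h or 18 h, with 3 libraries in each of the 6 groups. At 6 h the libraries held 11468476 to 29348455 counts in regions for vehicle, 16463585 to 36993461 for 0.1 nM and 21015917 to 33726875 for 10 nM. At 18 h they held 15735470 to 25588387 for vehicle, 8865035 to 30593974 for 0.1 nM and 8756311 to 39984217 for 10 nM. The 5000 regions with the most counts took a smaller share of the counts with 10 nM (34.1% ± 0.568 at 6 h and 33.8% ± 3.15 at 18 h, SD, n = 3) than with vehicle (39.1% ± 2.29 and 38.2% ± 1.90). In a principal component analysis of log2 CPM, the first component held 43.5% of the variance and the second 19.6%.

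**Figure D1:**
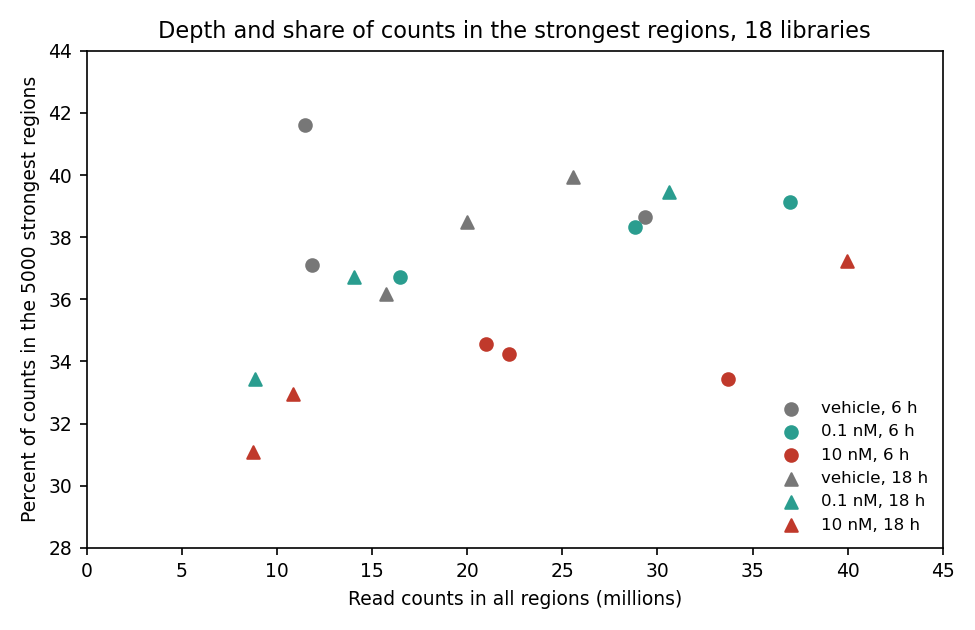
Percent of counts in the 5000 strongest regions (vertical axis) against read counts in all regions (horizontal axis), 1 point per library, circles for 6 h and triangles for 18 h. The 10 nM libraries at 6 h lie between 33.4% and 34.6%, below every vehicle library, and replicate 1 of the 10 nM group at 18 h stands apart from its group at 39984217 counts and 37.2%.

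Cells given 10 nM R5020 for 6 h differed from vehicle cells at 33262 of 132304 tested regions, or 25.1%: 22119 regions were more accessible and 11143 were less accessible. The regions that gained accessibility were weak in vehicle cells and rose by a median log2 fold change of 1.93, 10249 of them by at least 4-fold. The regions that lost accessibility fell by 1.13 at the median. The largest rise among named regions, from 0.186 ± 0.262 CPM to 7.98 ± 0.888 CPM (SD, n = 3), was on chromosome 18 from 56213329 to 56213669, 45.5-fold (edgeR adjusted p = 5.19e-07). On chromosome 11, the region from 113632598 to 113633131 went from 0.976 ± 0.283 CPM to 33.7 ± 2.17 CPM, a log2 fold change of 5.18 (SE 0.32). On chromosome 12, accessibility from 112483811 to 112484343 rose from 0.509 ± 0.157 CPM to 18.3 ± 1.77 CPM. The 8 named gains were 32.9-fold to 45.5-fold and 340 to 730 bp wide. Among losses, the region on chromosome 5 from 117345299 to 117346389 fell from 31.8 ± 6.23 CPM to 1.27 ± 0.156 CPM, 24.7-fold (edgeR adjusted p = 2.91e-09). A pair of named losses lay on chromosome X, from 78127975 to 78128639 and from 78213767 to 78214490, falling 25.5-fold and 20.9-fold. Accessibility on chromosome 13 from 57102240 to 57103191 fell 21.8-fold, from 14.4 ± 1.68 CPM to 0.63 ± 0.284 CPM. The 8 named losses were 18.0-fold to 25.5-fold and 664 to 1090 bp wide. All 16 named regions were called in the same direction by 10 nM at 18 h. The share of counts in the strongest regions, given above, differed between these groups in the direction of the gains. The number of regions that lost accessibility fell to 6547, 7107 and 7011 without replicate 1, 2 and 3 of the 10 nM group, to 6477 and 7318 without replicate 1 and 2 of the vehicle group, and to 6728 at a log2 fold change of at least 1.

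**Figure D2:**
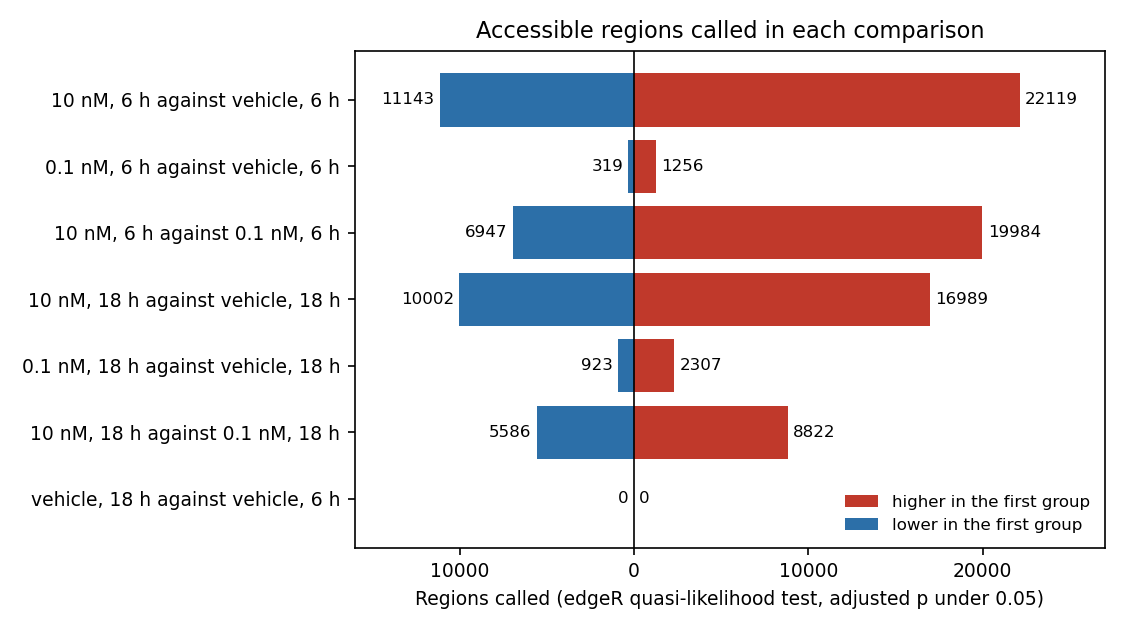
Number of regions called higher (bars to the right) and lower (bars to the left) in the first-named group of each comparison, by edgeR's quasi-likelihood test at an adjusted p under 0.05. The 10 nM dose against vehicle gave 22119 and 11143 regions at 6 h, 0.1 nM gave 1256 and 319, and the vehicle groups of the 2 times gave 0.

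At 0.1 nM for 6 h, 1256 regions were more accessible than in vehicle cells and 319 were less accessible, 1.19% of the regions tested. Median log2 fold changes of these regions were 1.56 and -1.27. Among named gains, the highest level was on chromosome 8 from 124417554 to 124418344, which rose from 2.00 ± 0.839 CPM to 27.8 ± 3.19 CPM, 13.6-fold (edgeR adjusted p = 9.3e-07). With 10 nM this region stood at 24.7 ± 0.93 CPM, and the doses did not differ there by the test (log2 difference -0.17, SE 0.24). The region on chromosome 1 from 86000211 to 86000723 rose from 0.952 ± 0.538 CPM to 13.0 ± 4.01 CPM, and the region on chromosome 6 from 3675524 to 3675953 rose 18.3-fold from 0.211 ± 0.249 CPM to 3.9 ± 0.605 CPM. On chromosome 2, the region from 223317182 to 223317733 rose 13.7-fold. Named losses were smaller, from 4.01-fold to 6.97-fold. The largest, on chromosome 1 from 191122047 to 191123063, fell from 23.6 ± 14.8 CPM to 3.35 ± 0.0168 CPM, and with 10 nM the level was 10.4 ± 3.12 CPM, higher than with 0.1 nM (edgeR adjusted p = 0.00754). Of the 8 named gains, 8 were also called higher with 10 nM at 6 h, and of the 8 named losses 7 were also called lower. The named losses on chromosome 5 from 100627911 to 100628751 and on chromosome 7 from 108556002 to 108556746 missed the threshold without replicate 1 or 3 of the 0.1 nM group or replicate 1 or 2 of the vehicle group, and the former also with the 2 libraries that lay apart left out, with edgeR adjusted p values up to 0.149. The counts of gains and losses fell to 632 and 86 without replicate 1 of the 0.1 nM group, 776 and 151 without its replicate 3, 641 and 70 without replicate 1 of the vehicle group and 557 and 102 without its replicate 2. Losses fell to 140 without replicate 2 of the 0.1 nM group. A fit of the compared groups alone called 837 and 206, the covariate for the share of counts in the strongest regions gave 2881 and 1065, and DESeq2's Wald test called 671 losses. Losses numbered 131 with the 2 libraries that lay apart left out.

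The doses compared directly at 6 h differed at 26931 regions: 19984 were higher with 10 nM and 6947 were lower. A gain present at 10 nM and not at 0.1 nM was seen on chromosome 6 from 139445293 to 139445751, with 7.78 ± 0.842 CPM at 10 nM, 0.212 ± 0.15 CPM at 0.1 nM and 0.327 ± 0.215 CPM with vehicle. Another on chromosome 1 from 174911068 to 174911397 stood at 9.9 ± 1.85 CPM with 10 nM and 0.317 ± 0.294 CPM with 0.1 nM, 35.6-fold apart (edgeR adjusted p = 1.72e-07). A further gain, on chromosome 1 from 210759938 to 210760406, was 35.3-fold. In the other direction, the region on chromosome 13 from 33919718 to 33920251 stood at 0.9 ± 0.296 CPM with 10 nM, 8.32 ± 1.32 CPM with 0.1 nM and 12.7 ± 1.57 CPM with vehicle. The chromosome X region from 78213767 to 78214490 was 10.5-fold lower with 10 nM than with 0.1 nM, and a region on chromosome 6 from 49630604 to 49630984 was 9.58-fold lower. Of the 22119 regions that gained accessibility with 10 nM, 76.0% were also higher with 10 nM than with 0.1 nM, and of the 11143 that lost it 45.5% were also lower than with 0.1 nM. Of the 1256 regions raised by 0.1 nM, 370 were higher still with 10 nM, 174 were lower with 10 nM than with 0.1 nM, and the rest did not pass the test of the dose difference. The number of regions lower with 10 nM fell to 4068 and 3760 without replicate 1 and 3 of the 0.1 nM group and to 3847, 4266 and 4333 without replicate 1, 2 and 3 of the 10 nM group. It was 3730 at a log2 fold change of at least 1, and 11622 with the share of counts in the strongest regions as a covariate.

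After 18 h, 10 nM R5020 left 16989 regions more accessible and 10002 less accessible than vehicle, 20.4% of those tested, with median log2 fold changes of 1.79 and -1.22. The largest named gain, on chromosome 5 from 76353354 to 76353893, went from 0.735 ± 0.247 CPM to 29.2 ± 9.47 CPM, 40.0-fold (edgeR adjusted p = 8.81e-08). The chromosome 6 region from 139445293 to 139445751, which rose at 6 h, stood at 7.95 ± 3.11 CPM against 0.255 ± 0.17 CPM. A region on chromosome 8 from 68071401 to 68071735 rose 31.5-fold, from 0.4 ± 0.136 CPM to 12.4 ± 3.98 CPM. The loss on chromosome 5 from 117345299 to 117346389 was again among the largest, from 22.6 ± 3.53 CPM to 1.07 ± 0.38 CPM, 20.9-fold. On chromosome 10, the region from 49220025 to 49220547 fell from 3.1 ± 0.676 CPM to 0.133 ± 0.0524 CPM, and at 6 h 10 nM had left it at 1.62 ± 0.605 CPM against 3.59 ± 0.345 CPM with vehicle. All 16 named regions were called in the same direction by 10 nM at 6 h. Libraries of the 10 nM group at 18 h spread more than at 6 h, with a median SD of log2 CPM of 0.453 against 0.237. Without replicate 1 of the 10 nM group, the share of gains among the calls went from 62.9% to 48.1%, with 14135 gains and 15261 losses, and without replicate 1 of the vehicle group 11250 and 6407 were called. Losses numbered 16120 with the 2 libraries that lay apart left out, 15096 with the covariate for the share of counts in the strongest regions, 6593 at a log2 fold change of at least 1 and 6259 in a fit of the compared groups alone.

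At 0.1 nM for 18 h, 2307 regions were more accessible and 923 were less accessible than with vehicle, 2.44% of the regions tested. The chromosome 8 region from 124417554 to 124418344 rose again, from 2.5 ± 0.998 CPM to 28.9 ± 5.18 CPM, 11.7-fold (edgeR adjusted p = 1.02e-06), with 31.0 ± 4.65 CPM at 10 nM. On chromosome 1, the region from 110391512 to 110392485 rose from 1.41 ± 0.319 CPM to 20.5 ± 3.78 CPM with 0.1 nM and stood at 10.8 ± 1.69 CPM with 10 nM, lower than with 0.1 nM by 0.92 on the log2 scale (edgeR adjusted p = 0.00351). On chromosome 6, accessibility from 137368175 to 137368532 rose 14.8-fold. The largest loss was again on chromosome 1 from 191122047 to 191123063, 13.0-fold, and the region on chromosome 14 from 37747878 to 37748632 fell 12.3-fold, from 12.3 ± 3.52 CPM to 0.888 ± 0.632 CPM. The chromosome 5 region from 117345299 to 117346389 fell from 22.6 ± 3.53 CPM to 3.23 ± 0.425 CPM, and another region on the same chromosome from 117474811 to 117475813 fell 6.41-fold. Of the 8 named gains 8 were also called higher with 10 nM at 18 h, and of the 8 named losses 8 were also called lower. Gains and losses numbered 1020 and 562 without replicate 1 of the 0.1 nM group, 957 and 335 without replicate 1 of the vehicle group and 1113 and 491 without its replicate 2, and losses fell to 398 and 604 without replicate 2 and 3 of the 0.1 nM group. With the covariate for the share of counts in the strongest regions, 4743 gains and 1689 losses were called.

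The doses compared at 18 h differed at 14408 regions, 8822 higher and 5586 lower with 10 nM. The chromosome 6 region from 139445293 to 139445751 was 32.6-fold higher with 10 nM than with 0.1 nM (edgeR adjusted p = 1.07e-05), and the region on chromosome 5 from 32263069 to 32263596 was 23.9-fold higher. The region on chromosome 4 from 52750349 to 52750698 was 31.0-fold higher. On chromosome 10, the region from 49220025 to 49220547 was 21.7-fold lower with 10 nM, with 2.97 ± 0.145 CPM at 0.1 nM, and the region on chromosome 12 from 97930202 to 97930677 was 7.58-fold lower. Of the 2307 regions raised by 0.1 nM at this time, 359 were higher still with 10 nM and 478 were lower with 10 nM than with 0.1 nM. Another split of these 6 libraries, which put replicate 3 of the 0.1 nM group with replicate 2 and 3 of the 10 nM group, called 13850 regions; those libraries were the 3 with the fewest counts at this time. With the replicate number as a block the doses differed at 11717 and 7933 regions, without replicate 1 of the 0.1 nM group at 5030 and 2953, and in a fit of the compared groups alone at 4505 and 1677. The number higher with 10 nM was 5619 without replicate 2 of the 0.1 nM group, 5384 without replicate 1 of the 10 nM group and 5698 with the 2 libraries that lay apart left out. The covariate gave 9411 lower.

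**Figure D3:**
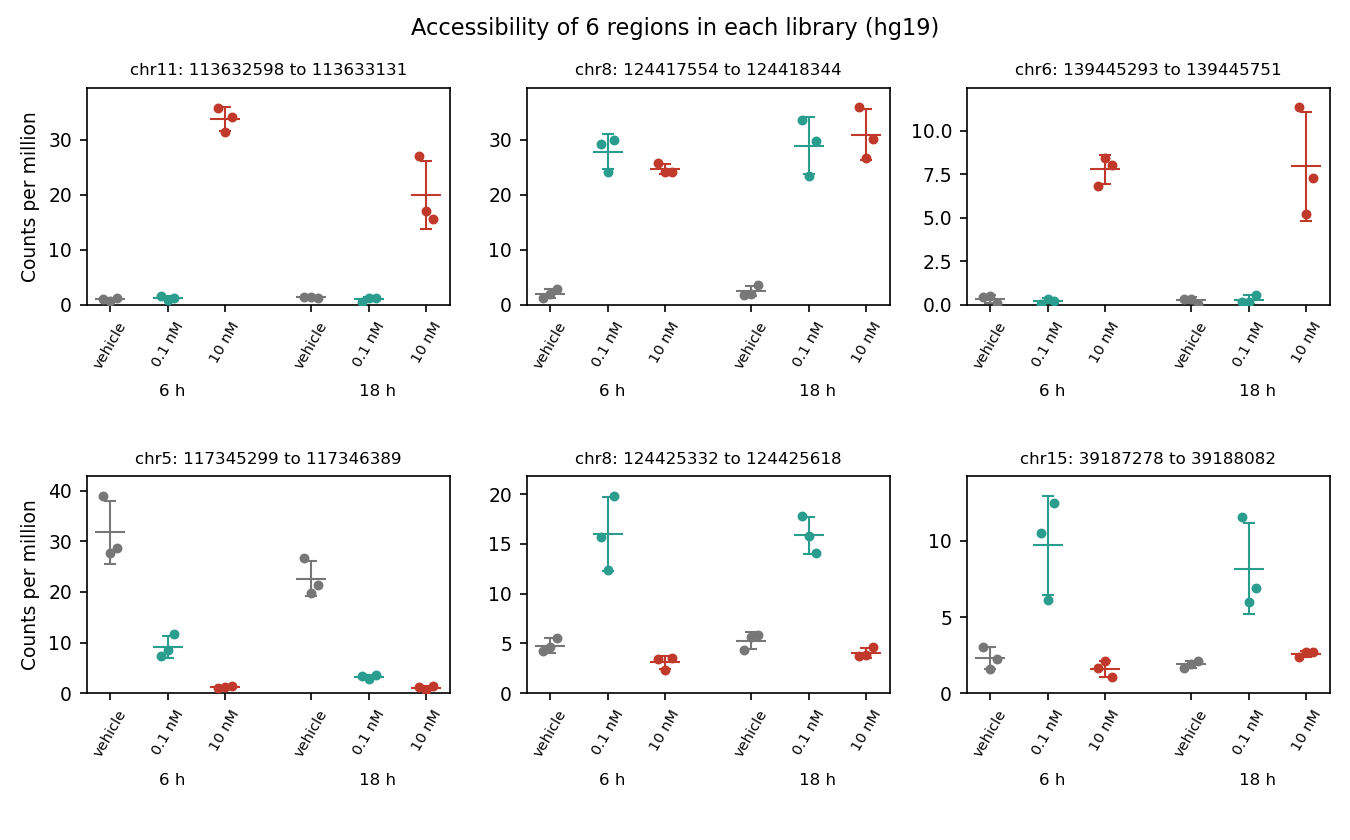
Accessibility in CPM (vertical axes, each from 0) of 6 regions in every library, grouped by treatment and time, with points for libraries and a line and bar for the mean and SD (n = 3). The regions on chromosome 11 and 6 are high with 10 nM, the chromosome 8 region that starts at 124417554 has 27.8 CPM with 0.1 nM and 24.7 CPM with 10 nM at 6 h, and the chromosome 5 region falls from 31.8 CPM with vehicle to 9.17 CPM with 0.1 nM and 1.27 CPM with 10 nM at 6 h. The last 2 regions stand highest with 0.1 nM at both times and were chosen after their values were seen.

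The responses to the doses overlapped. At 6 h, 1082 regions rose with both doses, 86.1% of those raised by 0.1 nM, and 300 fell with both, 94.0% of those lowered by 0.1 nM; independent lists of the same lengths would share 210 and 26.9. At 18 h the shared counts were 1624 and 865, beside 296 and 69.8. Both doses were set against the same vehicle libraries. In draws without change, where the doses shared simulated vehicle libraries, 0 calls were shared in each of 10 draws per time. That value is chance with no effect and does not measure what sharing adds where regions change. Across regions, which are not independent replicates, the log2 fold changes of the doses correlated with r = 0.44 at 6 h and 0.60 at 18 h. The draws without change gave 0.55 and 0.48. Covariance of the log2 fold changes was 0.243 and 0.311, above the simulated 0.132 and 0.108 by 0.111 and 0.202. The draws hold no shift of a whole vehicle library across regions, so this excess cannot be read as a response beyond sharing. The 3 vehicle libraries of a time are too few to split, so part of the overlap may come from sharing them. Across times, where no library is shared, 982 of the 1256 regions raised and 301 of the 319 lowered by 0.1 nM at 6 h were called in the same direction with 10 nM at 18 h. With an adjusted p under 0.01 the shared counts were 554 and 83 at 6 h and 733 and 330 at 18 h.

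The responses at the 2 times, which share no libraries, overlapped as well. With 10 nM, 13449 regions rose at both times and 6493 fell at both, where independent lists would share 2840 and 842, and 17 regions were called in opposite directions. With 0.1 nM the counts were 887 and 231, where independent lists would share 21.9 and 2.23. At an adjusted p under 0.01 these counts were 8308 and 3577 for 10 nM and 429 and 74 for 0.1 nM. A total of 722 regions rose in every one of the 4 comparisons with vehicle, and 220 fell in every one. The 22119 regions that gained accessibility with 10 nM at 6 h had, in the libraries of 18 h, a median log2 ratio to vehicle of 1.32 ± 0.16 with 10 nM and 0.34 ± 0.31 with 0.1 nM (SD of library medians, n = 3). The medians of the 0.1 nM libraries were 0.04, 0.32 and 0.65, where the strongest regions held 39.4%, 36.7% and 33.4% of the counts, and without replicate 3 the mean was 0.18. The 11143 that lost it stood at -0.93 ± 0.04 and -0.31 ± 0.10. The 1256 regions raised by 0.1 nM at 6 h stood at 1.30 ± 0.22 with 0.1 nM and 1.48 ± 0.21 with 10 nM at 18 h. In same-numbered pairs of libraries 10 nM was higher by 0.16, 0.10 and 0.26 (two-sided exact sign-flip permutation p = 0.25, the smallest that 3 pairs allow; unpaired exact permutation p = 0.4). The 319 regions lowered by 0.1 nM at 6 h stood at -1.33 ± 0.06 with 0.1 nM and at -2.15 ± 0.09 with 10 nM at 18 h, with pair differences of -0.91, -0.88 and -0.69 (two-sided exact sign-flip permutation p = 0.25, the smallest possible; unpaired 0.1, the smallest that 3 against 3 libraries allow).

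**Figure D4:**
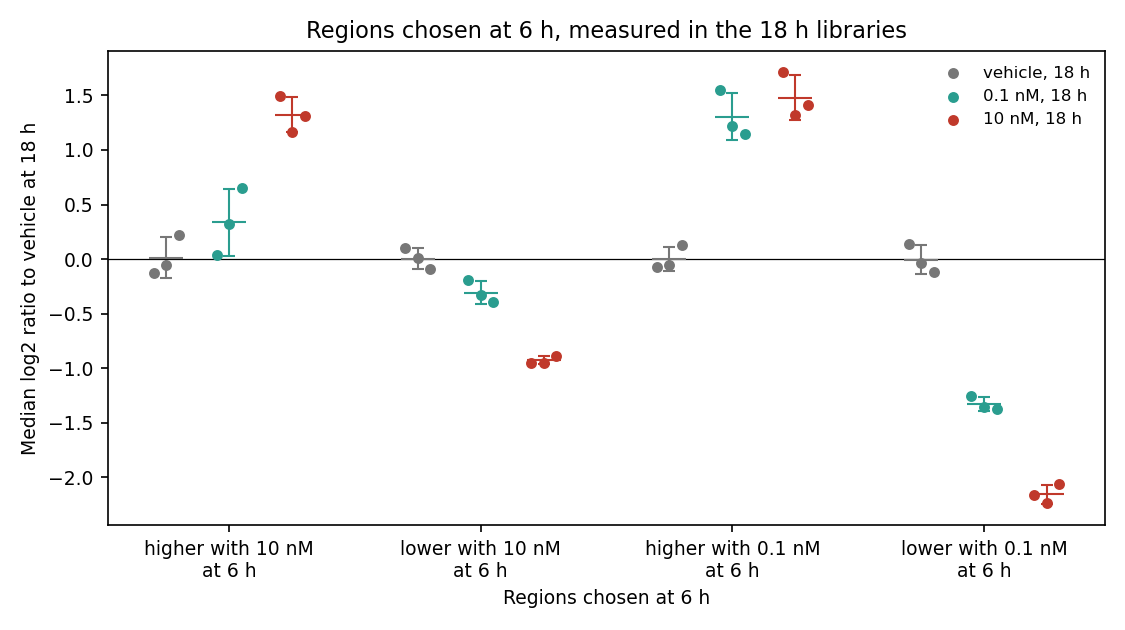
Median log2 ratio to the mean of the 18 h vehicle libraries (vertical axis) of 4 sets of regions chosen at 6 h (horizontal axis), 1 point per 18 h library with mean and SD (n = 3). Regions raised by 0.1 nM reach 1.30 with 0.1 nM and 1.48 with 10 nM, and regions raised by 10 nM reach 0.34 with 0.1 nM and 1.32 with 10 nM.

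Time alone changed little that the test could detect. Between the vehicle groups of 18 h and 6 h edgeR called 0 regions and DESeq2's Wald test called 0. By edgeR, 3796 regions, 2.87%, had an unadjusted p under 0.05. With the replicate number as a block edgeR called 0, and 7151 regions had an unadjusted p under 0.05. The response to 10 nM differed between the times at 2 regions, both lower at 18 h relative to 6 h, and the response to 0.1 nM at 0 regions by edgeR and 0 by DESeq2, with 3352 at an unadjusted p under 0.05. The region on chromosome 2 from 86181916 to 86182603 rose with 10 nM at 6 h, from 5.65 ± 0.761 CPM to 14.9 ± 3.44 CPM, and fell at 18 h, from 7.19 ± 1.06 CPM to 3.72 ± 0.873 CPM (edgeR adjusted p of the difference = 0.0462). The region on chromosome 17 from 53665309 to 53666337 stood at 23.2 ± 2.07 CPM with 10 nM and 16.7 ± 1.89 CPM with vehicle at 6 h, and at 5.83 ± 1.5 CPM and 16.8 ± 0.786 CPM at 18 h. The difference between the doses changed with time at 15 regions, each with a smaller value of 10 nM relative to 0.1 nM at 18 h. The lowest adjusted p among them (0.00253 by edgeR) was that of the region on chromosome X from 149864672 to 149865293, with 22.2 ± 2.42 CPM at 10 nM and 10.2 ± 0.696 CPM at 0.1 nM at 6 h, and 6.76 ± 1.12 CPM and 15.8 ± 1.33 CPM at 18 h. The count of 2 ranged from 0 to 63 and the count of 15 from 1 to 75 when libraries were left out in turn, both being highest without replicate 1 of the 10 nM group at 18 h. DESeq2's Wald test called 247 and 368, and the covariate 604 and 608. With the replicate block 179 and 194 regions were called lower at 18 h relative to 6 h, and 10 and 1 higher. Without the 2 libraries that lay apart the counts were 83 and 118.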

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

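Chosen after the results were seen were the tests that use the share of counts in the strongest regions, the count after loess normalization as a test of a trend, the place of held-out libraries, and the adjustment of library medians for that share. Of the results, 2 were picked out because a response differed between the times by a test of the difference itself.

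The response to 10 nM differed between 6 h and 18 h at 2 regions. The chromosome 2 region from 86181916 to 86182603 passed the test in opposite directions at the 2 times, with log2 fold changes of 1.41 (SE 0.23) at 6 h and -0.92 (SE 0.23) at 18 h. The chromosome 17 region from 53665309 to 53666337 had 0.47 (SE 0.19), not called, at 6 h and -1.53 (SE 0.20) at 18 h. These 2 regions lost their call in 22 of 40 values from alternative settings, with edgeR adjusted p values up to 0.189, and the count was 0 with DESeq2 size factors. The dose difference changed at 15 regions. On chromosome 17, the region from 72432427 to 72432862 had 10.7 ± 1.03 CPM with 10 nM against 1.31 ± 0.298 CPM with 0.1 nM at 6 h, and 1.44 ± 0.417 CPM against 1.82 ± 0.866 CPM at 18 h. With the share of counts in the strongest regions as a covariate the count of 15 became 608, and all 15 regions kept their call, with differences from -1.47 to -3.14. The mean share with 10 nM and 0.1 nM was 34.1% and 38.1% at 6 h, and 33.8% and 36.5% at 18 h. The gap between the doses changed little, so the covariate could move these differences only slightly. The 15 regions were also called in the same libraries. This test therefore cannot decide whether a lower share in some 18 h libraries was a source. These 15 regions lost their call in 150 of 300 values from alternative settings.

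More regions gained than lost accessibility with 10 nM. A candidate explanation is spread of reads to weak regions, as the 10 nM libraries held a smaller share of counts in the strongest regions. With that share as a covariate, 24374 regions were higher and 15971 lower at 6 h, so gains still outnumbered losses. These were partly other regions: 72.9% of the 22119 gains and 57.5% of the 11143 losses kept their call. A general rise of the weakest regions was tested on the 26461 with the lowest mean, whose median log2 fold change of 0.437 lay under the bound of 0.5 set beforehand by less than the SD of 0.0699 between libraries, with a mean of library medians of 0.501, so that test alone settled nothing; loess normalization, added later, removes a trend with mean level and left 20392 higher and 13387 lower. At 18 h, in libraries that did not choose the set, the lowest of the 3 library medians with 10 nM was 1.17, above the bound of 0.5, but a low share alone may pass it, as replicate 3 of 0.1 nM did at 0.65. With the share as a covariate over the 9 libraries of 18 h, the difference between 10 nM and vehicle was 1.14 (SE 0.23). With a library left out it was 0.616 to 1.26. The 0.616 came without replicate 1 of 10 nM, a library apart from its group. The unadjusted mean of the other 10 nM medians was 1.24. Spread reads are argued against as the whole source, but how much the share accounts for rests on that library. A partial contribution stays open, because the share itself may change with treatment, and that 10 nM R5020 opens many weak regions is a hypothesis from these data.

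Leaving out replicate 1 of the 10 nM group at 18 h took the share of gains from 62.9% to 48.1%, while thinning its 39984217 counts to the mean depth of the other 2 libraries left the share at 61.7%, so depth is argued against. That the library might hold cells treated for 6 h was tested by its place between the 6 h level (0) and the 18 h level (1), with a mean position of 0.641, between the bounds of 0.25 and 0.75 set beforehand, so that test alone settled nothing. On 200 regions ranked without each 6 h library in turn, held-out 6 h libraries lay at 0.0293 to 0.0608 and replicate 1 at 0.605 to 0.631, which argues against a plain 6 h sample. Other values go the opposite way: over all regions its log2 CPM correlated with the 10 nM libraries of 6 h at Spearman's rho of 0.900 to 0.917 and with its own group at 0.807 to 0.811, at depths that were not matched, and on the first 2 principal components it lay nearer the 6 h libraries. Ranked without the 18 h libraries, those lay at 0.674 and 0.684 and replicate 1 at 0.463 and 0.490, so it was not a typical 18 h library either; what sets this library apart stays open, including a mixture of samples and a difference between cultures, which were not tested.

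Other splits of the 6 libraries of a comparison number 10 with the real one, so no share can fall under 0.05. Each other split mixes libraries of the compared groups, which widens the spread within groups wherever regions respond. Few calls are then likely from the start, so these splits give no chance level for the number of calls. As many regions as in the real split were called in 1 of 10 splits, the real one, for each comparison of a dose with vehicle, for the doses at each time, and for the changes with time of the 10 nM response and of the dose difference. The highest other split called 0 regions for these, beside 33262 and 1575 for 10 nM and 0.1 nM against vehicle at 6 h, 26991 and 3230 at 18 h, 26931 between the doses at 6 h, 2 and 15. The exception was the dose comparison at 18 h, with 14408 regions in the real split and 13850 in that of the 3 shallowest libraries against the others, which points to a structure of the libraries; the blocked fit called 11717 and 7933. For the vehicle between times and the change of the 0.1 nM response with time the real split called 0, and so did each of the 10.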

How the results depend on the processing

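The covariate for the share of counts in the strongest regions, the fits without the 2 libraries apart (replicate 1 of 10 nM at 18 h and replicate 1 of vehicle at 6 h) and without the 100 strongest regions, and the changes to the sets measured at the other time were chosen after seeing the data. Counts that stayed within 1.5 times are left out; the cause of a moved count was not tested, except that fits of the compared groups or with a library less rest on fewer libraries. For gains and losses with 10 nM at 6 h, losses were 6728 at a log2 fold change of at least 1. For 0.1 nM at 6 h, gains and losses were 1925 and 747 with the replicate block, 2881 and 1065 with the covariate and 837 and 206 with the compared groups alone, and losses 131 without the libraries apart and 671 with DESeq2's Wald test. Losses of 10 nM against 0.1 nM at 6 h were 3730 at a log2 fold change of at least 1 and 11622 with the covariate. Losses with 10 nM at 18 h were 6593 at a log2 fold change of at least 1, 15588 with the block, 15096 with the covariate, 16120 without the libraries apart and 6259 with the compared groups alone. For 0.1 nM at 18 h, gains and losses were 3640 and 1732 with the block and 4743 and 1689 with the covariate. For the doses at 18 h they were 4505 and 1677 with the compared groups alone, with 9411 losses under the covariate and 5698 gains without the libraries apart. The change of the 10 nM response with time was called at 0 regions with DESeq2 size factors, 27 with library totals, 189 with the block, 604 with the covariate, 83 without the libraries apart and 247 with DESeq2's Wald test; that of the dose difference at 195 with the block, 608 with the covariate, 118 without the libraries apart, 26 without the 100 strongest regions and 368 with DESeq2's Wald test. At an adjusted p under 0.01, shared gains and losses of the doses were 554 and 83 at 6 h and 733 and 330 at 18 h, and those of the times 8308 and 3577 for 10 nM and 429 and 74 for 0.1 nM. Leaving out 1 library at a time gave gains of 16345 to 22446 and losses of 6477 to 12289 for 10 nM at 6 h, 557 to 1233 and 70 to 464 for 0.1 nM at 6 h, 14910 to 21122 and 3760 to 6319 between the doses at 6 h, 11250 to 16383 and 6407 to 15261 for 10 nM at 18 h, 957 to 2370 and 335 to 682 for 0.1 nM at 18 h, and 5030 to 9587 and 2953 to 6007 between the doses at 18 h, 0 to 63 for the 10 nM response with time, 1 to 75 for the dose difference with time, and 0 to 0 for the 0.1 nM response with time and for vehicle. The share of gains moved by no more than 10 points under another scaling; library totals shifted the median log2 fold change of all regions to 0.17 for 10 nM at 18 h. No region called higher in a main comparison was called lower in an alternative, or the reverse. The 93 values of named regions and of regions called between times kept their direction in all 1632 alternatives. These regions were chosen by large or called changes in the same libraries, so a change of sign was unlikely from the start. A call was lost in 181 of the alternatives, 9 of them in 2 losses with 0.1 nM at 6 h and the others in the changes with time. Outside the doses at 18 h and the vehicle groups the replicate numbers did not meet the limit for pairing, and there the block raised the counts given above; it also took the regions higher with 0.1 nM than with vehicle and than with 10 nM from 174 to 341 at 6 h, 478 to 871 at 18 h and 87 to 178 at both times, and it moved no other count of calls by more than 1.5 times. Every library correlated best with its own number between vehicle and 0.1 nM at 18 h, a hint from the data alone. Gene lists and motifs, and the alternatives for them, were not run. Small changes were mostly missed in the simulation, with 4 to 11 of 100 simulated 2-fold changes called. The simulation changed far fewer regions than were called with 10 nM, and the adjusted p limit is stricter when fewer regions change. It therefore does not give the share of small changes missed with 10 nM. At 6 h, 6728 of the 11143 losses with 10 nM were at least 2-fold, so smaller losses were also called.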

Other observations

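Chosen after the results were seen were the descriptions of level and width, the windows, the regions named below as highest with 0.1 nM, and the use of the 174 regions in place of a failed test of the 0.1 nM hypothesis.

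Regions that gained and lost accessibility with 10 nM at 6 h differed in their level with vehicle and in width. Those that gained had a median of 1.08 CPM in vehicle libraries and a median width of 389 bp, against 2.13 CPM and 387 bp for all tested regions. Those that lost had a median of 5.56 CPM and a width of 601 bp. The vehicle libraries of 6 h also chose these regions, so this order of levels was partly fixed by the choice. In the vehicle libraries of 18 h, which did not choose them, the medians were 1.19 CPM for gains and 5.18 CPM for losses. With 10 nM at 6 h the order was reversed, at 3.87 CPM for gains and 2.56 CPM for losses, beside 2.42 CPM for all tested regions. By mean level, 16.3% of the 26461 weakest regions gained and 2.47% lost, while of the 26461 strongest 9.92% gained and 12.1% lost. In the groups of about that size between them, from weak to strong, 19.3%, 19.3% and 18.9% gained and 5.32%, 8.60% and 13.6% lost. Gains were thus not most frequent among the weakest regions. The median log2 fold change of all regions in a group fell steadily, from 0.44 for the weakest to -0.29 for the strongest. Regions raised by 0.1 nM at 6 h were stronger in vehicle cells than those raised by 10 nM, with a median of 2.38 CPM and a width of 561.5 bp, and regions lowered by 0.1 nM had 8.38 CPM and 803 bp. Weak regions need a larger fold to be called, so these medians also reflect the power of the test.

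Gains and losses also lay near their own kind. The hypothesis that regions gaining accessibility with 10 nM lie in clusters was tested at 6 h: 31.2% of them had another such region within 10 kb, against 18.5% to 20.8% in 1000 shuffles of the calls among regions of the same chromosome and mean level (permutation p = 0.001, the smallest these shuffles can give). For regions losing accessibility the share was 21.3%, against 10.6% to 13.6% (permutation p = 0.001). Both hypotheses passed. On chromosome 2 between 11702307 and 11795908, 15 of 22 regions gained accessibility at 6 h and 6 at 18 h, with 0 losses at either time. On chromosome 5 between 32204639 and 32285191, 12 of 20 gained at 6 h and 8 at 18 h. On chromosome 9 between 13023010 and 13089436, 10 of 11 regions lost accessibility at 6 h and 8 at 18 h, with a median log2 fold change of -1.53 at 6 h for 10 nM and 0.01 for 0.1 nM. These windows were picked as being among those with the most gains or losses. The 31.2% and 21.3% lie above every shuffle, but they cover all gains and losses and do not test single windows. The shuffles did not match the width of regions or how densely they lie. Such windows may hold regions that share regulation, but a cluster may also reflect wide open domains cut into several regions, which was not tested.

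A set of regions stood higher with 0.1 nM than with either vehicle or 10 nM. At 6 h 174 regions met both tests, at 18 h 478, and 87 did at both times. Against vehicle at 6 h, 10 nM left the 174 at a median log2 fold change of 0.37, with 49 called higher and 9 lower. For the 478 at 18 h the median was 0.09, with 50 called higher and 30 lower. The regions named below were among those with the largest dose differences. Each stood lower with 10 nM than with vehicle at 6 h, which was not typical of the set. On chromosome 8, the region from 124425332 to 124425618 rose with 0.1 nM by 1.74 on the log2 scale at 6 h, from 4.8 ± 0.712 CPM with vehicle, while 10 nM left 3.1 ± 0.678 CPM; the levels with 0.1 nM, vehicle and 10 nM were 15.9 ± 1.85 CPM, 5.29 ± 0.818 CPM and 4.08 ± 0.508 CPM at 18 h (SD, n = 3). It lies near the region from 124417554 to 124418344, which rose with either dose. On chromosome 15, the region from 39187278 to 39188082 had 9.72 ± 3.24 CPM with 0.1 nM at 6 h, 2.3 ± 0.732 CPM with vehicle and 1.6 ± 0.506 CPM with 10 nM. On chromosome 8, the region from 40203395 to 40204601 had 21.7 ± 0.828 CPM, 11.6 ± 1.68 CPM and 3.88 ± 0.454 CPM, and at 18 h it had 20.6 ± 3.86 CPM with 0.1 nM and 5.94 ± 0.928 CPM with 10 nM, so that at 6 h 10 nM and 0.1 nM moved it in opposite directions from vehicle. The region on chromosome 6 from 49644329 to 49645750 had 27.4 ± 5.99 CPM, 14.4 ± 3.54 CPM and 8.12 ± 0.215 CPM at 6 h.

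The hypothesis is that some regions raised by 0.1 nM respond less to 10 nM. The test set beforehand asked whether, among the 1256 regions raised by 0.1 nM at 6 h, more were lower than higher with 10 nM against 0.1 nM at 18 h; 157 were lower and 270 higher, so the prediction as written failed, and a lower response was not the course of most. That bound asked for a majority, which a hypothesis about some regions does not need: 102 of the 174 regions chosen at 6 h were called lower at 18 h and 0 higher. Both comparisons use the 0.1 nM libraries, and chance highs in these could make such a set. Measured in the 18 h libraries, which did not choose it, the set of 174 kept a median log2 difference between 10 nM and 0.1 nM of -0.92, with library medians from -1.13 to -0.70, all under the bound of -0.5. The set of 478 chosen at 18 h had a median of -0.76 at 6 h, with 262 called lower and 3 higher. Selection noise is thus argued against for most of the set, and a response that peaks between vehicle and 10 nM remains a hypothesis. Of the 87 regions, 74 were found again after loess normalization, 84 with DESeq2's Wald test, 68 with the covariate for the share of counts in the strongest regions and 26 in fits of the compared groups alone. The set at 6 h went from 174 to 281 with the covariate, 69 and 67 without replicate 1 and 3 of the 0.1 nM group, and 108 and 87 without replicate 1 and 2 of the vehicle group. The set at 18 h went from 478 to 859 with the covariate, 208 in fits of the compared groups alone, 134 and 302 without replicate 1 and 2 of the 0.1 nM group, and 222 and 250 without replicate 1 and 2 of the vehicle group. The total at both times was 140 with the covariate, 41 without replicate 1 of the 0.1 nM group at 18 h, 43 and 39 without its replicate 1 and 3 at 6 h, and 57 and 48 without replicate 1 and 2 of the vehicle group at 6 h.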
